A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

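RNA from affinity selections of budding yeast (Saccharomyces cerevisiae) was measured on 8 oligonucleotide arrays of the Affymetrix Yeast Genome S98 design. Per the labels, 4 arrays held RNA recovered with TAP-tagged Upf1p and 4 held RNA from mock selections run in parallel, with replicates numbered 1 to 4 in each group. Cells grew in rich medium (YEPD), were ground in liquid nitrogen, and the cleared extract was bound to IgG Sepharose. TEV protease released the bound material, and its RNA was purified and labelled with biotin, per the labels' protocols. Equivalent amounts of tagged and mock RNA entered the last purification step, so the values speak of composition and not of yield. RNA of the whole extract was not analysed here.

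The authors deposited 1 table of array intensity values on a linear scale, with 9335 probe sets and 8 columns, each matched to a sample by its name. The submitters' processing notes name GCOS, the array maker's software, with no version. The notes give no further setting. The deposited values had been scaled before deposit, as the values themselves show: the trimmed mean of every array, leaving out 2% at each end, lay between 250.2 and 250.3. No value was missing or at 0. Detection calls and scanner files were not used here. Intensities give no molecule counts, and the number of arrays limits the precision.

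Control probe sets (60) were left out of all tests and described apart, which left 9275. A platform annotation table gave 1 gene for 6504 of these, several genes for 328 and none for 2443. Symbols were updated through a RefSeq gene table. No gene was named for a probe set with several genes or none, and such probe sets stayed in the test. The 6504 probe sets covered 5656 genes, of which 315 had more than 1 probe set. Coding length is the span in the gene table, 96.3% of which were whole multiples of the codon length.

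The analysis used log2(intensity + 4.09), the offset being the 10th percentile of all tested values. Fold changes are on this scale and understate the change of dim transcripts. limma 3.58.1 in R 4.3.3 fitted the group with the pair as a block, and eBayes used an intensity trend. Adjusted p-values are Benjamini-Hochberg over the 9275 probe sets, two-sided, with a threshold of 0.05. SE is limma's moderated standard error of the log2 ratio. The series' design text speaks of independent pairs of selections, and the pair is the replicate number. As a check of the pairing, deviations from the group means were correlated over the 4637 brighter probe sets. Arrays of the same number gave r between 0.18 and 0.55, other combinations gave r between -0.54 and 0.35, and 5 of 8 arrays correlated best with their own number. The labels do not say whether cultures were separate beyond this, so the p-values measure the spread between these selections.

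Gene lists were written before the data were examined, from general knowledge of yeast. Some genes stand on more than 1 list, so the list results are not independent. EST3 is on the substrate, frameshift and telomere lists, and REC107 and HFM1 are on the substrate and meiotic intron lists. NIT1 and YIL165C are on the substrate list and that of interrupted reading frames. ALR1, CTR2 and FRE2 are on the substrate and metal transport lists. Of 39 lists, 35 had at least 3 measured genes. The lists of intron-containing genes outside the ribosome, Y' helicases, Ty elements and tRNAs matched no measured probe set under their written rules. tRNA genes and Ty elements were then tested apart, as groups added after the data were seen. Each list was tested with camera (preset correlation 0.01), on 1 probe set per gene, with Benjamini-Hochberg adjustment over the 35 lists. The probe set was a plain one before one whose name marks shared sequence, then the brightest. Camera with an estimated correlation and fry were alternatives. fry tests whether a list's genes move on balance in 1 direction and does not compare them with other genes. With 4 pairs the estimated correlation rests on few residual degrees of freedom. With that option camera takes its p-value from them too, and it could hardly call any list here. A call it ends is thus not shown to come from genes that vary together.

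Genes were named by a rule written before the data were examined. It took NAM7, NMD2 and UPF3 in any case. It took up to 12 genes with the largest ratio in each direction among those past the threshold, with the same direction in all 4 pairs, a probe set of exactly 1 gene, and a level above the median probe set in the higher group. A gene with several such probe sets was shown by the one with the largest ratio in that direction. It took up to 4 members of each list with the smallest p. Genes named outside this rule are said to be so. The relation of the ratio to the mock level and to coding length was described as a correlation across genes, per pair, with the mock level taken from the other pairs. GC content and codon usage were planned too and were not run, because they need a genome sequence, which was not used here. No coordinates are given for the same reason.

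Alternatives planned before the data were examined were no pair block, quantile normalization, median centring, no offset, an offset at the 25th percentile, a filter on dim probe sets, eBayes without the trend or with the robust option, each pair left out in turn, other thresholds, and the mean of a gene's probe sets. The method was tested on simulated data made from the spread of these 9275 probe sets, with 50 probe sets changed by each amount. It recovered 84% and 92% of those changed by log2 ratios of -2 and 2, and 10% and 24% of those changed by -1 and 1. Among 108 calls in that test, 2.78% were false. A list shifted by 0.5 was found, and 0 of 20 unshifted lists were called. The simulated noise was independent between probe sets, so this does not give the rate of false list calls where genes vary together. The real comparison gave 2891 calls, so its limit on the unadjusted p was less strict and the recovered shares need not hold there. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.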

Results

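The study asked which yeast transcripts are bound with Upf1p, the RNA helicase at the centre of nonsense-mediated mRNA decay (NMD). NMD is the pathway that degrades mRNAs whose translation stops too early. Upf1p carried a TAP tag, a tandem affinity tag that binds IgG, and RNA recovered with it on 4 arrays was compared with RNA from mock selections on 4 arrays. The values are scaled intensities. The median signal of an array lay between 58.7 and 77.9, and the 100 brightest probe sets held between 18.9% and 30.0% of its summed signal. Pearson correlations of log2 signal were 0.95 to 0.98 within the Upf1p-TAP arrays, 0.97 to 0.98 within the mock arrays and 0.90 to 0.94 between the groups. The first principal component held 59.9% of the variance and separated the groups, and the second held 15.5%.

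Transcripts of the tagged gene itself were lower in the Upf1p-TAP selections. NAM7, which encodes Upf1p, had a signal of 14.1 ± 6.24 with the tag and 50.5 ± 20.4 in the mock (SD, n = 4). The log2 ratio was -1.59 (SE 0.25, adjusted p = 0.00178) and lay below 0 in 4 of 4 pairs. The mean NAM7 signal with the tag lay below the 25th percentile of all values, so the size of its ratio rests partly on the offset. Where its probe set (9566_at) lies relative to the tag is not given in the sources used here. NMD2 and UPF3, the other core NMD factors, had ratios of -0.04 and -0.17 that did not pass the test. NMD4 (log2 ratio 1.62) and EBS1 (1.17), which encode accessory NMD proteins, were higher. As a list the 5 factors were not called (median -0.04, adjusted p = 0.739).

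The transcript with the highest ratio under the naming rule was that of ISC10, a gene needed for sporulation. Its signal was 1703 ± 60.2 against 148 ± 52.3 in the mock (SD, n = 4), a log2 ratio of 3.54 (SE 0.22, adjusted p = 3.77e-05). SDL1 (3.36), annotated as a pseudogene, CNM1 (3.33), YBP1 (3.27), HIS3 (3.17, probe set 8360_at), the peroxisomal lipase gene LPX1 (3.12), RRT13 (3.08), YER187W (3.06), YNL162W-A (3.02), YGR127W (3.01), YOL029C (3.00) and SHU2 (3.00) followed. At the other end stood the small nucleolar RNAs SNR3 (-3.00), SNR72 (-2.99), SNR37 (-2.88), SNR66 (-2.74), SNR64 (-2.74), SNR45 (-2.70), SNR56 (-2.60) and SNR11 (-2.57). The ribosomal RNAs RDN37-1 (-3.48, SE 0.67) and RDN25-1 (-3.43, SE 0.71) had larger mean changes that varied widely, from -6.63 to -1.47 and from -6.52 to -1.08 over the pairs, each lowest in pair 2. The drug pump gene PDR5 (-2.64, probe set 2641_g_at) and mitochondrial COX1 (-2.62) were the others of the 12. All of these had an adjusted p below the threshold and 1 direction in 4 of 4 pairs. The RDN37-1 probe set is not called without the pair block (adjusted p = 0.0676), and repeated rRNA genes share its sequence. The mean Upf1p-TAP signals of SNR66 (13.5), SNR64 (13.1) and PDR5 (13.1) lay below the 25th percentile of all values, so the size of their ratios rests partly on the offset.

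Over all 9275 probe sets, 1642 were higher and 1249 lower in the Upf1p-TAP selections, and 6384 did not pass. At least 2-fold changes were found for 939 higher and 558 lower probe sets, and at least 4-fold changes for 186 and 63. Among 5486 protein-coding genes, 1105 were higher and 755 lower. Higher probe sets made up 56.8% of the calls, against 49.6% after quantile normalization and 42.7% after centring each array on its median. That centring moved the median ratio of all probe sets from 0.00 to -0.14, so that the balance of directions is set by the scaling. Leaving out replicate 4 of both groups left 1076 higher and 775 lower. The median standard error of a log2 ratio was 0.23.

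**Figure D1:**
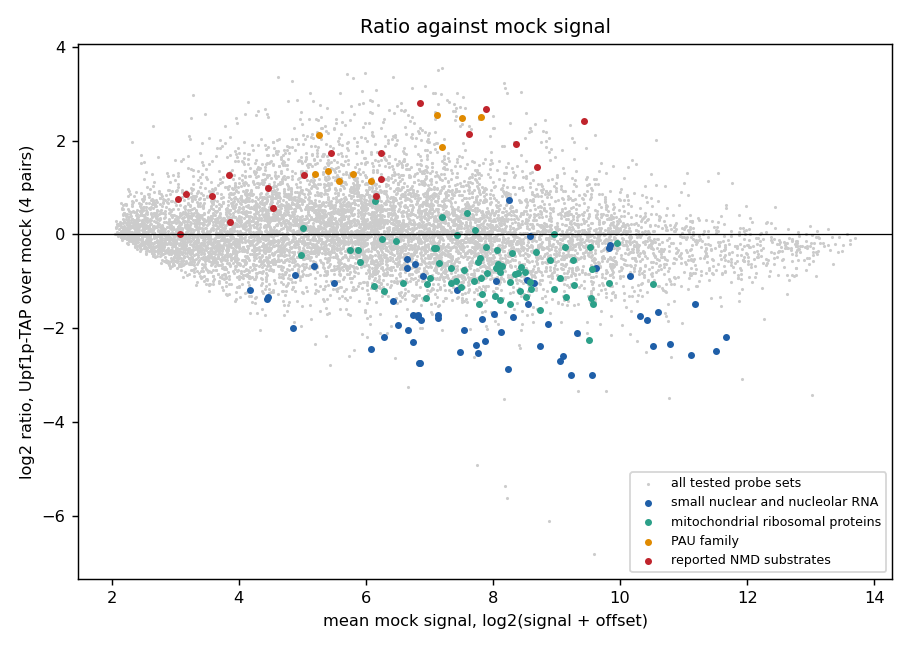
Each point is 1 probe set, with the mean mock signal as log2(signal + offset) on the x axis and the log2 ratio of Upf1p-TAP over mock, from 4 pairs, on the y axis. Reported NMD substrates (red, median 1.26) and PAU genes (orange, median 1.61) lie mostly above 0, while small nuclear and nucleolar RNAs (blue, median -1.78) and mitochondrial ribosomal protein genes (green, median -0.80) lie mostly below it.

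Transcripts reported earlier as NMD substrates were higher in the Upf1p-TAP selections. Of 19 measured, 15 were higher (16 adjusted over the list alone), 0 lower, and the median log2 ratio was 1.26. ALR1, which encodes a magnesium transporter, had a signal of 1528 ± 312 against 240 ± 62.6 in the mock, a log2 ratio of 2.66 (SE 0.17, adjusted p = 3.77e-05). CPA1, an arginine synthesis gene regulated by an upstream open reading frame, had 3780.5 ± 1019 against 703 ± 167, a ratio of 2.41 (SE 0.18, adjusted p = 4.50e-05). REC107, a meiotic gene with an intron, had a ratio of 2.80 on probe set 10998_at, while its second probe set, 10999_at, was at -0.52 and not called. The members that did not pass were CTF13 (-0.00), FRE2 (0.27), REV7 (0.57) and SPT10 (0.76), named here after their values were seen. CTF13 (4.56 against 4.38 in the mock), FRE2 (15.5 against 11.3) and SPT10 (10.3 against 4.53) lay below the 25th percentile of all values in both groups. A change at that level would be hard to see, though EST2 (12.5 against 4.91), 1 of the 15, was as dim. The calls of PPR1 (0.81), EST2 (0.85) and TEN1 (0.98) ended when 1 pair was left out. Their highest adjusted p was 0.116 (without replicate 1), 0.0965 (without replicate 2) and 0.126 (without replicate 1). UBP7 passed narrowly (0.83, adjusted p = 0.0474) and was not followed through the alternatives. PPR1, TEN1 and UBP7 were named after their values were seen. The list's shift passed camera (adjusted p = 2.04e-07), and gave adjusted p = 0.152 with an estimated correlation.

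Genes whose translation needs a programmed ribosomal frameshift were all higher: OAZ1 (2.09), which encodes ornithine decarboxylase antizyme, the telomerase subunit gene EST3 (1.92) and the actin-binding protein gene ABP140 (0.94). All 3 were higher adjusted over the list alone too, and together they had adjusted p = 0.00464, and adjusted p = 0.297 with an estimated correlation. Open reading frames that are interrupted in the reference strain were also higher, 10 of 17 (11 adjusted over the list alone) against 0 lower, with a median of 1.61 (1.02 with the mean of a gene's probe sets). NIT1 and YIL165C, named outside the naming rule, were among the higher ones and stand on the substrate list too. YOL162W had a ratio of 2.57, YOL153C 2.45, the aquaporin gene AQY2 2.14 and the metallothionein gene CRS5 1.61. The list had adjusted p = 3.15e-05, and adjusted p = 0.198 with an estimated correlation. Intron-containing meiotic genes gave 4 of 13 higher (4 adjusted over the list alone), namely REC107, REC102 (1.84), HFM1 (1.28) and SPO1 (0.88), and 0 lower. Their adjusted p was 0.0485, and adjusted p = 0.322 with an estimated correlation. The median was 0.44, and became 0.28 without replicate 3, 0.75 without an offset, 0.21 with the higher offset and 1.08 with the filter on dim probe sets. REC102 had 1.22 with the higher offset. The call ended without replicate 1, 2 or 3 (highest adjusted p = 0.120, without replicate 3), without an offset (adjusted p = 0.0538) and with the mean of a gene's probe sets (median 0.28, adjusted p = 0.0944), and the call of SPO1 ended without replicate 2 or 4 (highest adjusted p = 0.0612).

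Genes reported with upstream open reading frames went both ways, with 8 of 30 higher and 5 lower (9 and 5 adjusted over the list alone). Besides CPA1, the translation initiation factor gene TIF4631 (1.52), UGA3 (1.39) and the transporter gene HOL1 (1.16) were higher. LEU4 (-1.49), PET111 (-1.02), FOL1 (-0.75), SCO1 (-0.59) and IMD4 (-0.57), named after their values were seen, were lower. FOL1, SCO1 and IMD4 lost their calls when 1 pair was left out (highest adjusted p = 0.0919, 0.132 and 0.100, without replicate 4, 1 and 4). The list as a whole was not called (median 0.27, adjusted p = 0.116).

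**Figure D2:**
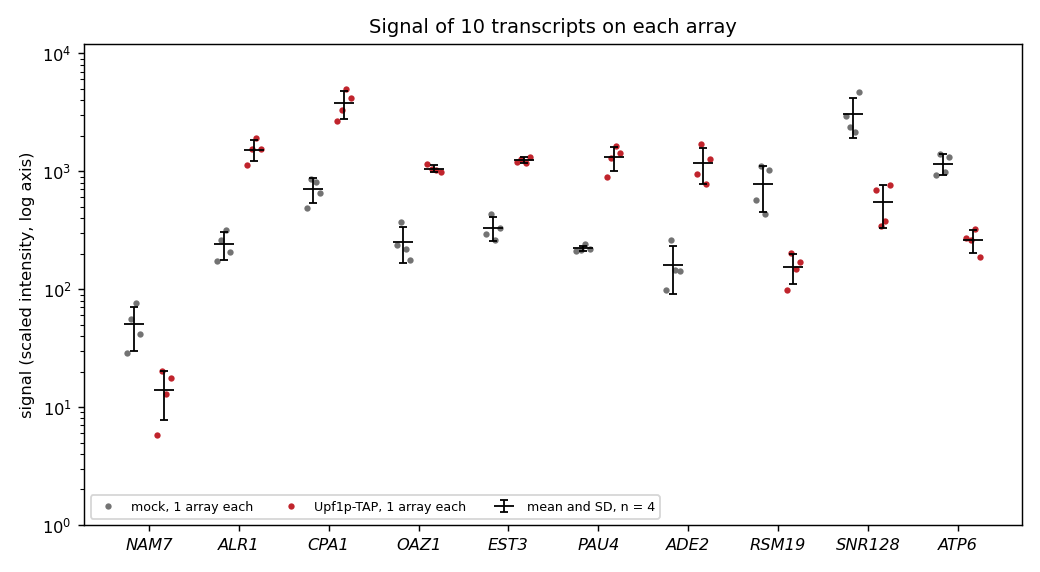
Signal of 10 transcripts on each array, on a log axis, with 1 point per array and the mean and SD of the 4 arrays of a group. NAM7, RSM19, SNR128 and ATP6 are lower with Upf1p-TAP, and ALR1, CPA1, OAZ1, EST3, PAU4 and ADE2 are higher, with no overlap between the groups.

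All 10 measured PAU genes, a family of subtelomeric mannoprotein-like genes, were higher (10 adjusted over the list alone), with a median of 1.61. PAU4 (2.51) and PAU13 (2.49) are examples. As a family they had adjusted p = 4.94e-07, and adjusted p = 0.152 with an estimated correlation. PAU genes are close copies, so their probe sets may read each other's transcripts. Meiosis and sporulation genes, which are little used in growing cells, gave 14 of 36 higher (14 adjusted over the list alone), among them SPS4 (1.86) and SPO21 (1.74), and 1 lower. The lower one was NDT80 (-0.69), named after its value was seen, whose call ended without any 1 of the pairs (highest adjusted p = 0.127, without replicate 3). This list had adjusted p = 5.32e-04, and adjusted p = 0.187 with an estimated correlation. Its median of 0.55 became 0.34 with the higher offset and 0.90 with the filter on dim probe sets.

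Genes commonly used as auxotrophic markers split sharply. ADE2 had a signal of 1175 ± 399 against 161 ± 69.8 in the mock (SD, n = 4), a log2 ratio of 2.86 (SE 0.20, adjusted p = 4.25e-05). HIS3 (2.63 and 3.17 on probe sets 8359_at and 8360_at), the arginine permease gene CAN1 (2.53), TRP1 (2.30) and LEU2 (1.10) were higher too, each in 4 of 4 pairs. URA3 (-0.29) and MET17 (-0.39) did not pass, and LYS2 was lower (-0.89, adjusted p = 0.0411). A control probe set of URA3, outside the test, had less signal with Upf1p-TAP in 4 of 4 pairs. LEU2, URA3, MET17 and LYS2 were named after their values were seen. The call of LYS2 ended without replicate 1, 3 or 4 (log2 ratios of -0.88, -0.55 and -0.98, highest adjusted p = 0.132, without replicate 3), and MET17 was called lower after median centring (-0.53, adjusted p = 0.0369). Of the 8, 5 were higher and 1 lower (5 and 2 adjusted over the list alone). Together the markers had adjusted p = 0.0230, and adjusted p = 0.297 with an estimated correlation.

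**Figure D3:**
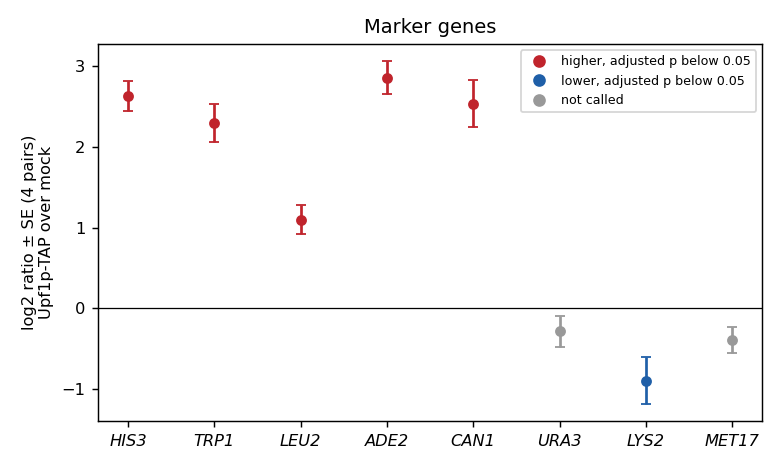
Log2 ratio of Upf1p-TAP over mock for the 8 marker genes, with the standard error from the fit to 4 pairs. HIS3, TRP1, LEU2, ADE2 and CAN1 lie between 1.10 and 2.86, and URA3, LYS2 and MET17 lie below 0.

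Further lists with higher ratios were metal transport, thiamine metabolism and allantoin catabolism. In metal transport, 8 of 32 were higher, ALR1 and the copper transporter gene CTR2 (1.43) among them, and SMF3 (-0.81) and ZRT1 (-0.54) were lower (8 and 2 adjusted over the list alone). With a median of 0.35 (0.20 after median centring), the list had adjusted p = 0.0228, and adjusted p = 0.504 with an estimated correlation. In thiamine metabolism, THI22 (1.67), THI20 (1.43), THI4 (1.24), THI3 (1.17) and THI7 (0.64) were higher and THI2 (-0.75), a regulator, was lower (6 and 1 adjusted over the list alone, of 11). Its adjusted p was 0.0209, and adjusted p = 0.297 with an estimated correlation. In allantoin catabolism, DAL3 (1.54), DAL7 (1.33), DAL5 (1.24), DAL2 (1.11) and DAL82 (0.79) were higher and 0 of 11 lower (5 adjusted over the list alone). Its median was 0.60 (0.40 with the higher offset) and its adjusted p 0.0455, and adjusted p = 0.548 with an estimated correlation. SMF3, ZRT1, THI7, THI2 and DAL82 were named after their values were seen. The allantoin list was not called without replicate 1, 2 or 4 (highest adjusted p = 0.0769, without replicate 4) or after quantile normalization (adjusted p = 0.0524), nor metal transport without replicate 2 (adjusted p = 0.0504). Leaving out 1 pair also ended the calls of SMF3 (-0.51 and highest adjusted p = 0.110, without replicate 3), ZRT1 (0.129, without replicate 2), THI2 (0.117, without replicate 1, with a ratio of -0.46 at the higher offset), THI7 (0.159, without replicate 2), DAL2 (0.0781, without replicate 4) and DAL82 (0.0905, without replicate 4).

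Small nuclear and nucleolar RNAs, which guide modification and processing of other RNAs in the nucleus, were lower in the Upf1p-TAP selections. Of 62 such and other noncoding RNAs, 51 were lower and 0 higher (54 and 1 adjusted over the list alone), with a median log2 ratio of -1.78. SNR128 fell from 3049 ± 1153 in the mock to 544 ± 215 (SD, n = 4), a ratio of -2.50 (SE 0.18, adjusted p = 4.17e-05), and SNR77 had a ratio of -2.19. Together these RNAs had adjusted p = 4.65e-24, and adjusted p = 0.303 with an estimated correlation. Genes of the mitochondrial genome, transcribed inside the organelle, gave 9 of 19 lower and 0 higher (10 and 0 adjusted over the list alone). OLI1 (-1.80), ATP6 (-2.13) and COX1 (-2.62) were bright, while COB (-2.46) had a mock signal of only 53.5. With Upf1p-TAP the COB signal was 6.24, near the offset, so the size of its ratio is uncertain. This list had adjusted p = 2.86e-05, and adjusted p = 0.297 with an estimated correlation. Its median of -0.74 became -1.80 without an offset, -0.28 with the higher offset and -2.30 with the filter on dim probe sets, and COB had -1.62 with the higher offset. Spike-in controls were lower on the Upf1p-TAP arrays as well. The median ratio of the 4 poly-A spikes, RNAs added before labelling, was -2.17, -3.71, -0.20 and -4.47 in pairs 1 to 4, with pair 3 near background on both arrays. Hybridization spikes, added after labelling, had a mean ratio of -0.77 ± 0.12 (SD over 4 pairs). Control probe sets for rRNA had mean ratios of -0.90 ± 1.46 (18S) and -0.66 ± 0.57 (25S).

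Nuclear genes for the mitochondrial ribosome were lower too, 44 of 70, and 0 were higher (46 and 1 adjusted over the list alone), with a median of -0.80. RSM19 had a signal of 155 ± 43.8 against 783 ± 328 in the mock, a ratio of -2.25 (SE 0.22, adjusted p = 1.44e-04), and MRPL23 had -1.62. As a group they had adjusted p = 9.56e-13, and adjusted p = 0.152 with an estimated correlation. Among cytoplasmic ribosomal protein genes, 26 of 82 were lower and 2 higher (26 and 2 adjusted over the list alone), with a median of -0.30. For comparison, the 1097 protein-coding genes with the highest mock signal had a median of -0.25, with 301 lower. No random lists matched on mock level were drawn for the ribosomal list. RPS7A (-1.27) and RPL3 (-1.17) were lower, whereas RPL22B (1.58) and RPL15B (0.74) were higher. RPL15B was named after its value was seen, and its call ended without replicate 2 (adjusted p = 0.0523). Many of these genes come in near-identical pairs, so their probe sets may not tell the copies apart. The list had adjusted p = 3.25e-07, adjusted p = 0.336 with an estimated correlation, and a median of -0.12 with adjusted p = 0.0637 after quantile normalization.

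Genes that build ribosomes and charge tRNAs moved the same way. In ribosome biogenesis 27 of 72 were lower, such as NOP56 (-1.44), and 4 higher (29 and 4 adjusted over the list alone). The 4 were IMP3 (1.51), SSF1 (0.93), MPP10 (0.87) and UTP4 (0.78). MPP10 and UTP4 lost their calls when 1 pair was left out (highest adjusted p = 0.0962, without replicate 2, and 0.108, without replicate 4). The list had a median of -0.44 and adjusted p = 1.83e-05, and adjusted p = 0.322 with an estimated correlation. Aminoacyl-tRNA synthetase genes gave 11 of 19 lower and 0 higher (11 and 0 adjusted over the list alone), VAS1 among them at -1.46. Their median was -0.62 and adjusted p = 1.37e-05, and adjusted p = 0.303 with an estimated correlation. In translation factors 12 of 32 were lower, and TIF4631, GCD11 (0.84) and HCR1 (0.80) were higher (13 and 4 adjusted over the list alone). With a median of -0.28 (-0.42 after median centring), this list had adjusted p = 0.0485, and adjusted p = 0.555 with an estimated correlation. It was not called after quantile normalization (adjusted p = 0.147), without the pair block (0.0507), without an offset (0.0518), with the filter on dim probe sets (0.0536), in eBayes without the trend (0.0516), or without replicate 1 (median -0.13, adjusted p = 0.0799) or 3 (median -0.33, adjusted p = 0.120). SSF1, MPP10, UTP4 and GCD11 were named after their values were seen.

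Among other lists, vacuolar ATPase, glycolysis, chaperone, proteasome and endoplasmic reticulum genes had medians of -0.51, -0.37, -0.56, -0.47 and -0.42. Vacuolar ATPase genes gave 7 of 16 lower and 0 higher (9 and 0 adjusted over the list alone), with VMA1 at -1.45, and had adjusted p = 5.22e-04, and adjusted p = 0.187 with an estimated correlation. Glycolysis and fermentation gave 9 of 19 lower, CDC19 at -0.73 among them, and 1 higher, PDC5 at 1.41 (10 and 1 adjusted over the list alone). Its adjusted p was 0.00257, and adjusted p = 0.297 with an estimated correlation. Of 24 chaperone genes, 12 were lower, HSP104 at -1.70 among them, and SSA3 (1.65) was higher (14 and 1 adjusted over the list alone), with adjusted p = 0.00408, and adjusted p = 0.426 with an estimated correlation. Of 34 proteasome genes, 13 were lower and PUP3 (0.61) was higher (16 and 2 adjusted over the list alone), with adjusted p = 0.00780, and adjusted p = 0.376 with an estimated correlation. Of 32 genes for translocation and glycosylation in the endoplasmic reticulum, 9 were lower and OST2 (0.76) was higher (9 and 1 adjusted over the list alone), with adjusted p = 0.0161, and adjusted p = 0.504 with an estimated correlation. PUP3 and OST2 were named after their values were seen. The last list was not called without replicate 3 (median -0.18, adjusted p = 0.0536), nor PUP3 without replicate 1, 3 or 4 (highest adjusted p = 0.101, without replicate 4), nor OST2 without replicate 1 or 4 (highest adjusted p = 0.119, without replicate 4). Glycolysis was not called after quantile normalization (adjusted p = 0.103).

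Amino acid synthesis genes were mixed, with 17 of 53 lower and 8 higher (18 and 8 adjusted over the list alone). HIS3 and CPA1 were among the higher ones, and the list had a median of -0.23 and adjusted p = 0.0399, and adjusted p = 0.385 with an estimated correlation. Ergosterol synthesis gave 6 of 22 lower and 0 higher (6 and 0 adjusted over the list alone), with a median of -0.21 and adjusted p = 0.0455, and adjusted p = 0.376 with an estimated correlation. The 1097 protein-coding genes with the highest mock signal had a median of -0.25, with 301 lower. Amino acid and ergosterol medians of this size may thus go with signal level alone, which was not tested. Cell wall genes gave 0 of 24 lower and 1 higher, TIR4 at 1.06 (0 and 1 adjusted over the list alone). Their median of -0.27 still had adjusted p = 0.0306, and adjusted p = 0.579 with an estimated correlation. After median centring the 3 medians were -0.38, -0.35 and -0.42. After quantile normalization none of these 3 lists was called (adjusted p = 0.135, 0.135 and 0.166). Leaving out 1 pair ended each call as well (highest adjusted p = 0.0618 without replicate 2 for amino acid synthesis, 0.0724 without replicate 3 for ergosterol, whose median was -0.14 without replicate 1, and 0.119 without replicate 1 for the cell wall).

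No shift was called for mating genes (median 0.36, adjusted p = 0.236), telomere maintenance (0.33, 0.0855), histones (0.34, 0.739), mRNA decay (-0.12, 0.0870), the TCA cycle and oxidative phosphorylation (0.05, 0.691), hexose transporters (-0.54, 0.0740) or the COS family (-0.04, 0.739). Some alternatives did call 3 of these: telomere maintenance higher with fry (adjusted p = 0.0444) and without replicate 3 (0.0495), hexose transporters lower with the filter on dim probe sets (0.0243) and without replicate 2 (0.0456), and mRNA decay lower after quantile normalization (0.0457). In pyrimidine synthesis the median was -0.21, the mean 0.01 and the adjusted p 0.757, with median and mean of opposite sign. In all, 10 lists were called higher and 15 lower, and 0 of the 25 kept the call with an estimated correlation. That option has few residual degrees of freedom and could hardly call any list, so these losses do not tell the lists apart.

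**Figure D4:**
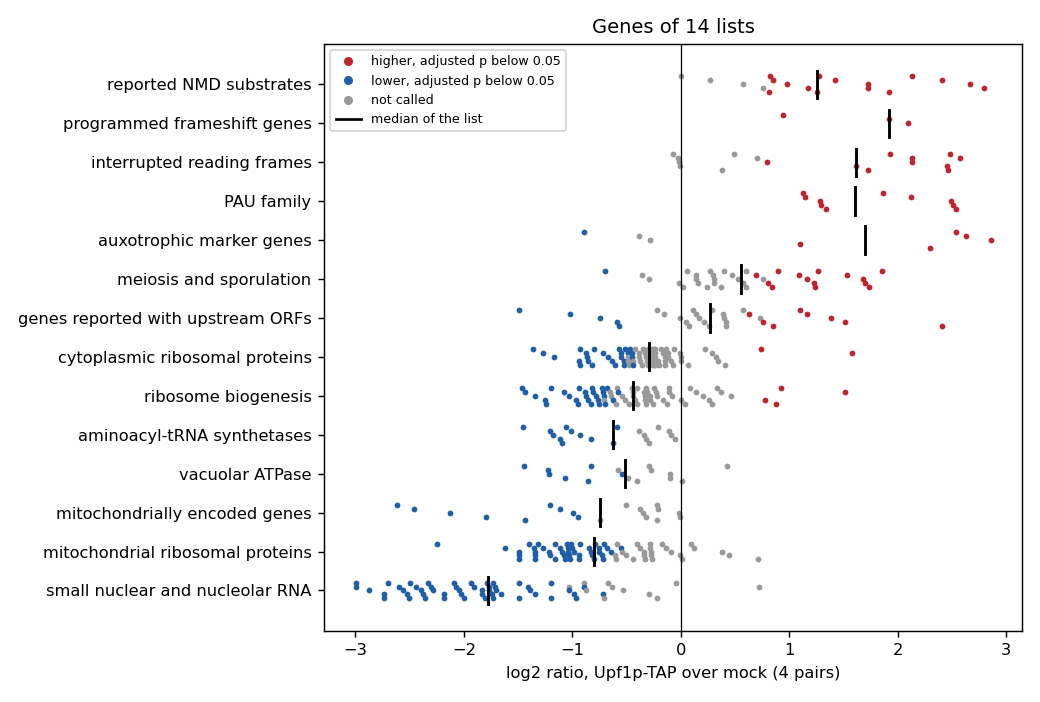
Log2 ratio of Upf1p-TAP over mock, from 4 pairs, for each measured gene of 14 lists, with the median of a list as a black bar. Reported NMD substrates, frameshift genes, interrupted reading frames and PAU genes have medians between 1.26 and 1.92, and the small nuclear and nucleolar RNAs have a median of -1.78.

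Dim transcripts had higher ratios than bright ones. Across 5486 protein-coding genes, Spearman's rho between the ratio of a pair and the mock level of the other pairs was -0.26 ± 0.05 (SD over 4 pairs), and Pearson's r was -0.24 ± 0.04. Genes are not independent replicates, and 2 properties were examined in this way. Among the 1098 genes with the lowest mock signal the median ratio was 0.30, with 272 higher and 32 lower. Among the 1097 genes with the highest it was -0.25, with 106 higher and 301 lower. Only the reported NMD substrates and the marker genes were set against random lists matched on mock level. For other lists, such as translation factors (-0.28), glycolysis (-0.37) and meiosis and sporulation (0.55), the part that signal level plays was not tested. For coding length rho was -0.01 ± 0.14 and r was -0.03 ± 0.13, smaller than the spread between pairs.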

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

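The control probe sets were looked at only after the comparison was known. In groups of 4 arrays, the highest or lowest value was set against the range of its group for each named transcript, list median and RNA quality measure. Of 275 groups, 13 held a value far from the others, where chance gives about 13.8.

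On Upf1p-TAP replicate 1, 5 transcripts were low: LPX1 at 1822 (others 2808 to 2824), NMD4 at 40.3 (others 133 to 160), FLO8 at 40.4 (others 154 to 159), UTP4 at 69.0 (others 95.6 to 99.0) and SPO1 at 16.0 (others 32.3 to 37.0). FLO8 was named after its values were seen. That array also had the highest ratio of 3' to 5' signal of the actin gene ACT1, 13.5, against 6.17 on mock replicate 1 and 1.99 to 3.37 on the other 6 arrays. On Upf1p-TAP replicate 3, YOL162W stood high at 122 (others 89.3 to 92.5), and SNR66 (8.41, others 14.8 to 15.5) and DAL2 (56.7, others 118 to 126) stood low. On Upf1p-TAP replicate 4, SNR64 (15.4, others 12.2 to 12.5) and SNR56 (162, others 66.1 to 75.1) stood high. In the mock, SNR72 was high in replicate 4 at 1924 (others 514 to 613) and YOL153C low in replicate 3 at 26.4 (others 34.8 to 36.3). The vacuolar ATPase list had a median ratio of -0.35 in pair 4, against -0.56 to -0.54 in the other pairs.

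Among the 60 control probe sets, which stood outside the test, 25 were lower with Upf1p-TAP in every pair, all 3 of ACT1 among them, and 3 were higher in every pair. AFFX-YER022w3_at had a mean of 90.5 against 54.9 in the mock, while the 5' and middle probe sets of the same transcript were lower in 4 of 4 pairs. Those lay near background on all arrays, with highest signals of 13.9 and 16.5. AFFX-YER148wM_at had 1272 against 964. AFFX-MurIL10_at had 1.66 against 1.04, both near background.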

How the results depend on the processing

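Every alternative here was planned before the data were examined. The counts of 1642 higher and 1249 lower probe sets became 940 and 524 at an adjusted p below 0.01, by the stricter threshold itself. Leaving out 1 pair gave 1076 to 1384 higher and 775 to 953 lower, lowest without replicate 4, with fewer samples in each fit. Without the replicate block, 1340 were higher and 931 lower, and 2240 of these 2271 were also called with the pairing, all in the same direction. That fit ended the calls of 12 of the 118 named probe sets and of 2 lists, and changed no other call among them. The 10 higher and 15 lower lists became 0 and 0 with an estimated correlation. The estimate was below the preset 0.01 for the PAU family (0.0017), meiosis and sporulation (0.0012), vacuolar ATPase (-0.045) and the marker genes (-0.053). A higher correlation between genes therefore does not account for these losses. With this option the p-value of every list rests on few residual degrees of freedom, which leaves hardly any list to be called. For other lists, such as the small nuclear and nucleolar RNAs (0.56), the estimate was higher too, and how much that adds was not tested. fry called 10 and 10, ending 6 calls (translation factors, amino acid synthesis, endoplasmic reticulum, allantoin, ergosterol and cell wall). Under quantile normalization, median centring, other offsets, the filter on dim probe sets and other variance models both counts of probe sets stayed within 1.5 times. No called gene or list changed direction under any alternative. Quantile normalization ended the calls of 7 lists and median centring of 0. Among named probe sets, the robust option ended 0 calls, the filter removed 5 probe sets and ended 0 calls among the 113 left, and leaving out replicate 1, 2, 3 or 4 ended 15, 16, 11 or 21. The offset sets the size of change in lists of dim genes: the mitochondrially encoded median of -0.74, with 3 of 19 members above a mean signal of 100, lay between -1.80 and -0.28 under other offsets, and the list stayed called. GC content and codon usage were not run.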

Other observations

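Tests of the tag's marker, of a deletion in the mock strain, of the relation to signal level and of a common dilution were chosen only after the results were seen, as were the tRNA and Ty element groups and the comparison of bright with near-absent probe sets.

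Transfer RNAs, grouped by their annotated type, went with the small nucleolar RNAs. Of 91 measured, 51 were lower in the Upf1p-TAP selections and 0 higher, with a median log2 ratio of -0.94 (camera p = 3.20e-15, and p = 0.249 with an estimated correlation). Ty retrotransposon probe sets gave 19 of 136 higher and 0 lower, with a median of 0.22 (p = 0.00161, and p = 0.435 with an estimated correlation). Of all 9275 probe sets 17.7% were higher, so the Ty elements had no larger share of higher calls. Their median was 0.59, 0.16, 0.46 and 0.01 in pairs 1 to 4. Ty elements are repeated, so their probe sets may read each other's transcripts. Of 14 probe sets for annotated pseudogenes, 7 were higher and 0 lower, with a median of 0.94. Within the telomere list, which was not called, the telomerase genes EST1 (1.26), EST2 (0.85) and EST3 (1.92) and the telomere capping genes STN1 (1.73), TEN1 (0.98) and CDC13 (0.92) were higher, and RAP1 (-0.67) was lower. With the higher offset EST1 had 0.80 and EST2 0.44, and EST2 had 1.30 without an offset and was not called after median centring (adjusted p = 0.0503). The calls of EST2, TEN1, CDC13 and RAP1 ended when 1 pair was left out (highest adjusted p = 0.0965 without replicate 2, 0.126 without replicate 1, 0.170 without replicate 2 and 0.0985 without replicate 3). TEN1, CDC13 and RAP1 were named after their values were seen. EST1, EST2, EST3, STN1 and TEN1 are also members of the list of reported NMD substrates, so their values are not a separate result.

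Some probe sets were bright in 1 group and near background in the other. With a mean signal above 100 on one side and below the 25th percentile of all values on the other, 9 were bright with the mock alone and 2 with Upf1p-TAP alone. The 9 include the nucleolar RNA probe sets of SNR64, SNR66 and SNR74, the last chosen after its values were seen, and 6 without a gene in the annotation used here. SNR74 was bright by its mean only, 109 ± 111 in the mock (SD, n = 4). Its lowest mock array was at 20.4 and its highest Upf1p-TAP array at 19.5. In 5 of the 6 without a gene, no Upf1p-TAP array exceeded 7.44 and no mock array lay under 60.4. Their signal with Upf1p-TAP is near the offset, so no ratio is given. An example is 3953_at, with 3.26 ± 3.46 against 769 ± 114 in the mock (SD, n = 4). What these probe sets read was not tested.

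Among 8 auxotrophic marker genes 5 were higher, so that 1 marker gene carried with the tag cannot account for all of them, though it stays open for any 1. A deletion in the mock strain is argued against for LEU2 by its mock signal of 3523 ± 618 (SD, n = 4; median probe set 65.6) and stays open for HIS3, TRP1, ADE2 and CAN1, of which 4 of 4 lay above that median (lowest 97.3), since levels of different probe sets compare only roughly. The relation to signal level gave 0.39 as the upper end of the 95% range of medians in 10000 random lists matched on mock level, against 1.70 observed. Another open hypothesis is that both strains carry nonsense or frameshift alleles of HIS3, TRP1, LEU2, ADE2 and CAN1, as a widely used laboratory background does, so that their mRNAs may be NMD substrates. HIS3, TRP1, LEU2, ADE2 and URA3 had been seen by then. For CAN1, LYS2 and MET17 the hypothesis foretold that CAN1 alone would be higher, and 3 of 3 came out so. Only 19.6% of the 5656 genes were called higher, so LYS2 and MET17 would most likely come out so in any case. The score thus rests on CAN1, and the strains' genotypes are not given in the sources used here.

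Noncoding and mitochondrial RNAs were lower with Upf1p-TAP. Scaling to 1 target may have set the overall balance. The small nuclear and nucleolar list kept its direction and call under quantile normalization and median centring (adjusted p at most 2.37e-20), though it had adjusted p = 0.303 with an estimated correlation. Camera compares a list with the other genes, so a shift common to all genes could hardly end this call. The list was thus low relative to other transcripts, and whether its absolute amount fell was not tested. A dilution of background RNA by 1 common factor would lower all groups alike. Over members with a mean signal above 100, the medians of small nucleolar RNAs (41 members, mean over pairs -1.86), tRNAs (55 members, -1.01) and mitochondrial mRNAs (3 members, -2.15) lay within 0.5 of each other in 0 of 4 pairs. The tRNAs stood apart (-0.38, -1.83, -0.36 and -1.47 in pairs 1 to 4). Small nucleolar (-1.42, -2.16, -1.25 and -2.60) and mitochondrial medians (-1.86, -2.39, -1.57 and -2.79) lay closer together, so a common factor for these groups alone stays open. Dilution by unequal factors, unequal labelling of RNAs without a poly-A tail and a compressed response of the array stay open and were not tested.

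Reported NMD substrates were higher (camera adjusted p = 2.04e-07, and adjusted p = 0.152 with an estimated correlation). This could follow from binding to Upf1p or from higher abundance in the tagged strain if the tag impaired NMD. The relation to signal level gave 0.50 as the upper end of the 95% range of medians in 10000 random lists matched on mock level, against 1.26 observed. If NMD were impaired, URA1 and URA4, which the substrate PPR1 activates, would be raised in the extract. Both were named for this prediction, outside the naming rule. URA1 was higher (0.73, adjusted p = 0.0298) and URA4 was not called (-0.70, adjusted p = 0.102), with a mean of 0.0151 for both; the call of URA1 ended without replicate 1, 2 or 4 (highest adjusted p = 0.122, without replicate 1), without the pair block (0.0698), in eBayes without the trend (0.0501) and after median centring (0.0568), where URA4 was called lower (-0.84, adjusted p = 0.0339). Of the 10 measured genes of pyrimidine synthesis, 4 were higher and 3 lower. URA10, which was not part of the prediction or followed through the alternatives, was among the higher ones (1.58, adjusted p = 8.07e-04). URA3, also outside the prediction, was not called (-0.29, adjusted p = 0.306). PPR1 itself was higher (0.81, adjusted p = 0.0311). Its call ended without replicate 1, 2 or 4, without the pair block (0.0632) and after quantile normalization (0.0552). Binding and abundance cannot be told apart here, because URA1 and URA4 disagree and the RNA of the whole extract was not analysed here.

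The number of calls in the fit without the pairs argues against chance, if the pairing is set aside. Of the 35 splits of the 8 arrays, 1, the real one, gave 2271 calls, and the highest of the others gave 3. These splits exchange arrays across pairs, and 1 of 35 is the smallest share they can give. With the pairs kept, the real labels gave 2891 calls and the highest of the other exchanges within pairs gave 0, and 1 of 8 is too large a share for this count to fall under 0.05.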
